A study of Homo sapiens with 8 samples.

How the data were processed

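Polyadenylated RNA was sequenced from 2 human osteosarcoma cell lines, 143B and HOS, in cells labelled as control (NC) or as carrying a guide against NAT10 (sgNAT10), on the BGISeq-500 platform per the labels' protocols. Each of the 4 groups held 2 libraries, 8 in all. The labels do not say whether the 2 libraries of a group came from separate cultures or separate guides, so p-values measure the spread between these samples, which may be technical.

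The authors deposited FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments), in a separate table for each cell line. The submitters' processing notes name Bowtie2, RSEM, DESeq2 and the genome build GRCh38, without versions or roles. The version of the gene annotation is not given in the sources used here. For 143B 12700 genes are listed and for HOS 12810, of which 11807 stand in both. Each listed gene has more than 0.5 FPKM in at least 2 libraries of its table, so a gene near the floor in a line can be listed in the other line alone. The tables give no read counts, and the low values showed no clear steps from which reads could be recovered, so depth is unknown and no counting interval is given. In their place, the listed FPKM summed to between 484793 and 798137 per library, and the Pearson correlation of log2(FPKM + 1) between the libraries of a group was 0.979 for 143B NC, 0.986 for 143B sgNAT10, 0.995 for HOS NC and 0.997 for HOS sgNAT10.

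From these values, log2(FPKM + 1) was computed, and genes with at least 1 FPKM in at least 2 of the 4 libraries of a line were tested with limma 3.58.1 in R 4.3.3 (moderated statistics with an intensity trend, two-sided, Benjamini-Hochberg adjusted p with a threshold of 0.05). Fold changes are on the log2(FPKM + 1) scale, which understates the changes of genes with low values. The lines were fitted separately, as sgNAT10 minus NC. A joint fit of the 4 group means, over genes passing the filter in both tables, gave the mean change over both lines and the difference between the lines (143B minus HOS), with differences always taken within a table first. The joint fit estimates the spread of each gene from both lines together, although replicates correlated more closely in HOS than in 143B. FPKM are not counts, so no count model was used. With 2 libraries against 2, an exact permutation test of a single value cannot go below p = 0.33, and the tests rest on the spread pooled across genes.

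Before the data were examined, 24 gene lists were fixed (pathways, complexes and markers of other cell types), as were the rule for the genes named and the alternatives. Lists with at least 5 tested members were tested with camera, with a preset correlation between genes of 0.01, and again with an estimated correlation and with fry. The rule names NAT10, then the 13 largest rises and the 13 largest falls of each line and of both lines, among genes past the threshold whose libraries of one label all lie above those of the other. It adds the 5 largest differences between lines in each direction, and 4 members of each list by their change over both lines. ATF4, THUMPD1, NME1 and NME2, and 13 gene families were chosen after their values were seen. Some genes that the rule names, and tests built on another gene chosen afterwards, are not reported here.

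The alternatives fixed beforehand were a pseudocount of 0.1 or 5, no filter or a filter at 5 FPKM, rescaling to a common sum, median-ratio scaling, quantile normalization, no intensity trend, robust moderation, an added 2-fold threshold, a replicate block, a spread shared by all 8 libraries, and leaving out each library. Added after seeing the data were a correction for transcript length and GC content (a spline with 4 degrees of freedom), the same with the block, a crossed block in HOS, and leaving out ribosomal protein and MTRNR2L genes before rescaling. The length and GC correction also recentres each library. Lengths, GC contents and gene positions came from a GENCODE annotation of GRCh38, to which 98.4% of the genes of the 143B table and 98.5% of those of the HOS table matched by name.

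The fits were tested on simulated data, 10 times, with 200 genes changed. In 143B, over 11419 genes, 24.8% of 2-fold changes (log2 of 1) and 98.7% of changes with a log2 of 2 were recovered, and 5.40% of calls were false. In HOS, over 11957 genes, these were 99.8%, 100% and 7.36%. Over both lines, with 10655 genes, they were 92.2%, 100% and 4.37%, and for the difference between lines 15.9%, 88.8% and 3.39%. The simulated noise was independent between genes, without shifts of whole libraries, and far fewer genes changed than the real fits called. These rates therefore need not hold for the real calls.

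Genes that share reads with near-identical copies are uncertain in tables of this kind: the MTRNR2L genes, which copy mitochondrial ribosomal RNA, the pseudogene RPSAP58, the histone HIST1H4 genes, EIF3C, TUBA1A, the actins ACTA2 and ACTG2, and NME1.NME2, a readthrough of the neighbours NME1 and NME2. None of the members of the list of mitochondrially encoded transcripts stood in the tables, and that list was not used here.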

Results

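RNA from 143B and HOS cells was profiled in control cells and in cells labelled sgNAT10, which the submitters describe as knockout cells. NAT10 is the acetyltransferase that places N4-acetylcytidine on RNA. 143B is a derivative of HOS, and both are established osteosarcoma lines. Each line had 2 control libraries (NC) and 2 libraries labelled sgNAT10. Median FPKM over the listed genes was 6.07 ± 1.62 (SD, n = 2) in 143B NC, 4.67 ± 0.643 in 143B sgNAT10, 8.64 ± 0.053 in HOS NC and 10.6 ± 0.127 in HOS sgNAT10. Read depth is unknown.

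NAT10 was lower in the libraries labelled sgNAT10 in 143B but not in HOS. The gene lies on chromosome 11, from 34105602 to 34147670 on the plus strand of GRCh38, and is annotated as protein coding. In 143B it stood at 16.06 and 19.95 FPKM in the control libraries and at 9.05 and 7.19 FPKM in those labelled sgNAT10, a log2 change of -1.06 (SE 0.31, adjusted p = 0.026). In HOS it stood at 14.9 and 16.2 FPKM in the controls and at 21.1 and 19.1 FPKM in the libraries labelled sgNAT10, a log2 change of 0.35 (SE 0.10, adjusted p = 0.0054). NAT10 RNA was thus not lower under the sgNAT10 label in HOS, and every HOS direction is drawn between the libraries as labelled. A guide that disrupts the protein need not lower the RNA, so the RNA level alone does not test the knockout. The 143B call was lost without NC replicate 2 (adjusted p = 0.064), without sgNAT10 replicate 1 (0.11), without sgNAT10 replicate 2 (0.22) and under median-ratio scaling (0.060). The HOS rise was lost without sgNAT10 replicate 1 (adjusted p = 0.18) and under median-ratio scaling (log2 0.14, adjusted p = 0.26), and after length and GC correction the value was -0.077.

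**Figure D1:**
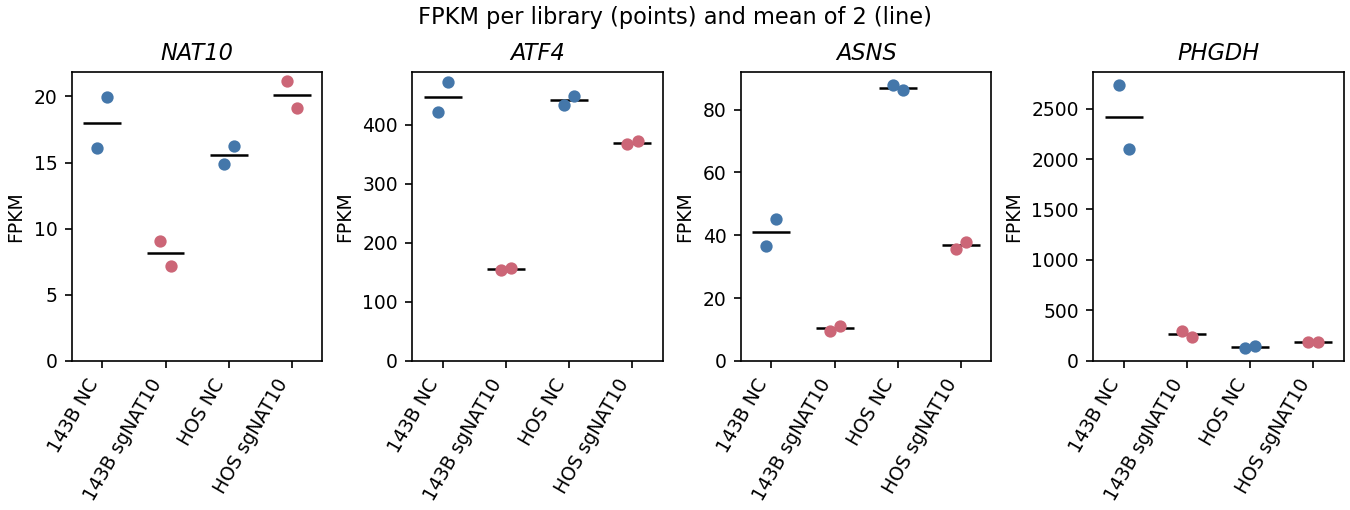
FPKM of 4 genes in each library (points, y axis from 0) with the mean of the 2 libraries of a group (line), in blue for NC and red for sgNAT10. NAT10 fell from a mean of 18.0 to 8.12 FPKM in 143B and stood at 15.5 and 20.1 FPKM in HOS, while ASNS was lower under the sgNAT10 label in both lines.

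In 143B, 4370 of 11419 genes changed, 1473 higher and 2897 lower in the libraries labelled sgNAT10, and 3426 of them by at least 2-fold. The falls were led by PLAT, tissue plasminogen activator, from 58.6 ± 6.84 to 1.26 ± 0.035 FPKM (SD, n = 2; log2 -4.71, SE 0.31, adjusted p = 0.00039). DDIT4, an inhibitor of mTORC1 signalling, fell from 55.1 ± 5.13 to 1.48 ± 0.25 FPKM (log2 -4.50). CDKN1A, the cell cycle inhibitor p21, fell from 108 ± 5.52 to 6.64 ± 0.042 FPKM (log2 -3.83), and PLAU, urokinase, from 456 ± 56.3 to 32.9 ± 2.71 FPKM (log2 -3.75). Also lower were CRABP1, which binds retinoic acid (log2 -4.29), the retinaldehyde reductase DHRS3 (log2 -4.09), and the transcription factors BHLHE40 (log2 -4.01) and HOXB8 (log2 -3.94). So were LPCAT4 (log2 -3.72), IL10RA (log2 -3.62) and LOC101929479 (log2 -3.68). Calls for the pseudogene RPSAP58 (log2 -3.72) and the readthrough NME1.NME2 (log2 -3.67) are uncertain, since they share reads with other genes.

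The rises in 143B included CAV1, the caveola protein caveolin-1, from 32.6 ± 11.7 to 355 ± 69.1 FPKM (log2 3.43, SE 0.30, adjusted p = 0.00089). PRKAR2A, a regulatory subunit of protein kinase A, rose from 10.3 ± 2.18 to 111 ± 8.56 FPKM (log2 3.32), and the phosphatase PTPN14 from 2.83 ± 0.339 to 32.4 ± 8.58 FPKM (log2 3.10). ZCRB1, a splicing protein (log2 3.11), the adhesion protein NEGR1 (log2 3.07) and ASB3 (log2 3.01) rose as well. PLD4 (log2 3.35), EIF4EBP3, which binds the cap-binding factor eIF4E (log2 3.22), ZAR1 (log2 3.05) and LOC105369205 (log2 4.27) also rose. HIST1H4J (log2 3.86), HIST1H4C (log2 3.10) and MTRNR2L3 (log2 4.15) rose too, with values that near-identical copies make uncertain. Without sgNAT10 replicate 1 the count was 2360 genes, and without sgNAT10 replicate 2 it was 1995, while with the replicate number as a block it was 7652. The median change over all genes was -0.25, and under median-ratio scaling, which brings it to -0.017, the split was 2361 higher and 2541 lower.

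Genes of amino acid supply and stress were lower together in 143B. Of 34 tested members of the ATF4 list, 20 fell and 1 rose (21 and 1 adjusted over the list alone). PHGDH, the first enzyme of serine synthesis, fell from 2417 ± 443 to 267 ± 40.7 FPKM (log2 -3.17, adjusted p = 0.00089). GDF15 (log2 -2.49) and ASNS, asparagine synthetase (log2 -1.88), fell too. ATF4 itself fell from 447 ± 36.6 to 155 ± 2.32 FPKM (log2 -1.52, adjusted p = 0.0027). The list stood below other genes by camera (adjusted p = 0.00096; adjusted p = 0.37 with an estimated correlation). Of the 18 genes for endoplasmic reticulum chaperones and the unfolded protein response, 11 fell and 0 rose (12 and 0 adjusted over the list alone). Among them were XBP1 (log2 -2.10), HYOU1 (log2 -2.09) and HSP90B1 (log2 -1.32), with adjusted p = 0.024 by camera and adjusted p = 0.64 with an estimated correlation. For hypoxia and glycolysis, 16 of 29 fell and 0 rose (17 and 0 adjusted over the list alone). ANGPTL4 (log2 -3.25) and VEGFA (log2 -2.47) were among them, with adjusted p = 0.00096 and adjusted p = 0.37 with an estimated correlation. Cholesterol genes fell in 9 of 24 cases and rose in 1 (9 and 1 adjusted over the list alone). IDI1 stood at -1.31, and the list had adjusted p = 0.035 (adjusted p = 0.55 with an estimated correlation; adjusted p = 0.11 without sgNAT10 replicate 1).

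Growth-factor response and matrix genes were lower in 143B as well. Of 18 immediate early genes 17 fell and 1 rose, the same counts as adjusted over the list alone. FOS (log2 -2.92), DUSP1 (log2 -2.65) and EGR1 (log2 -2.42) fell, and KLF6 was the member that rose (log2 2.56), with adjusted p = 2.2e-05 for the list and adjusted p = 0.55 with an estimated correlation. Inflammatory and NF-kB genes fell in 16 of 20 cases and rose in 2 (16 and 2 adjusted over the list alone). ICAM1 fell (log2 -3.08), as did IER3 (log2 -3.24), while CCL5 rose (log2 2.40), with adjusted p = 0.0022 for the list and adjusted p = 0.55 with an estimated correlation. In the list of extracellular matrix and mesenchymal genes, 21 of 35 fell and 1 rose (26 and 1 adjusted over the list alone). MMP14, a membrane matrix protease (log2 -3.02), TGFBI (log2 -2.57) and COL4A2 (log2 -2.44) fell, with adjusted p = 2.6e-05 and adjusted p = 0.55 with an estimated correlation. Of 11 osteoblast genes 7 fell and 0 rose, the same counts as adjusted over the list alone, with ALPL, the bone alkaline phosphatase, at -1.89 and MSX2 at -1.75. That list had adjusted p = 0.041 (adjusted p = 0.64 with an estimated correlation), and its call was lost without sgNAT10 replicate 1 (adjusted p = 0.067), with a pseudocount of 5 (0.065), when rescaled to a common sum (0.071) and after length and GC correction (0.13).

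Ribosome genes went the other way in 143B. Of 45 cytosolic ribosomal protein genes 19 rose and 2 fell (24 and 2 adjusted over the list alone). RPS3 rose from 1943 ± 483 to 5417 ± 241 FPKM while RPLP0 (log2 -1.28) and RPL30 (log2 -1.13) fell. The list had adjusted p = 5.4e-10 by camera, adjusted p = 0.32 with an estimated correlation and adjusted p = 0.20 under quantile normalization. Ribosomal protein genes took 26.2% ± 1.12 (SD, n = 2) of the listed FPKM in NC and 41.3% ± 0.927 in the libraries labelled sgNAT10. Of 34 ribosome biogenesis genes 9 rose and 3 fell, the same counts as adjusted over the list alone. Among them the snoRNP protein NOP58 rose (log2 2.19), as did the helicase DDX21 (log2 1.84), while NOP10 fell (log2 -1.58). That list had adjusted p = 0.041, adjusted p = 0.55 with an estimated correlation, and a median of 0.19 that became -0.14 when libraries were rescaled to a common sum.

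The other lists were not called in 143B. Higher and lower members numbered 4 and 7 of 20 for aminoacyl-tRNA synthetases, with SARS at -2.48, and 5 and 2 of 31 for RNA acetylation and modification enzymes. Within the latter list, YBX1, which binds 5-methylcytosine in RNA, fell from 314 ± 113 to 61.1 ± 18.8 FPKM (log2 -2.33, adjusted p = 0.0019). THUMPD1, the partner of NAT10 in tRNA acetylation, rose from 4.61 ± 2.24 to 13.6 ± 1.68 FPKM (log2 1.44, adjusted p = 0.017). The counts were 1 and 5 of 30 for DNA replication, 2 and 5 of 32 for mitosis, 2 and 6 of 19 for p53 targets, and 2 and 4 of 18 for YAP targets. They were 4 and 10 of 31 for the respiratory chain, 4 and 2 of 19 for interferon-stimulated genes, 3 and 2 of 13 for histones, 2 and 4 of 15 for heat shock and 0 and 2 of 7 for epithelial markers. Their adjusted p by camera lay between 0.094, for histones, and 0.98, for epithelial markers. Counts adjusted over the list alone were the same except for aminoacyl-tRNA synthetases (4 and 8), RNA modification enzymes (4 and 2), mitosis (1 and 1) and heat shock (2 and 5). Median and mean differed in sign for the respiratory chain (0.21 and -0.23, with SDHB at -2.37), for interferon-stimulated genes (-0.081 and 0.11) and for RNA modification enzymes (-0.035 and 0.040). The mitosis list had a median of -0.24 while the direction of its camera test, which was not called, was up. Several of these balances turned under another scaling: mitosis had 5 higher and 2 lower under median-ratio scaling, aminoacyl-tRNA synthetases 6 and 5 under quantile normalization, and DNA replication 12 and 7 after length and GC correction, as did epithelial markers (3 and 1). Rescaled to a common sum, RNA modification enzymes had 2 higher and 4 lower and interferon-stimulated genes 2 and 3. Of the other marker lists, 4 blood markers (1 higher, 2 lower) and 3 endothelial, adipose and neural markers (0 changed) were tested, too few for a list test.

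In HOS, 8195 of 11957 genes changed, 5444 higher and 2751 lower in the libraries labelled sgNAT10, and 688 of them by at least 2-fold. ESM1, a proteoglycan first found in endothelium, rose from 0.905 ± 0.11 to 14.9 ± 1.73 FPKM (SD, n = 2; log2 3.06, SE 0.12, adjusted p = 5.5e-12). MMP1, interstitial collagenase, rose from 7.21 ± 1.17 to 51.5 ± 2.12 FPKM (log2 2.68). SNAI1, a repressor of epithelial genes (log2 2.52), the growth factors GDNF (log2 2.46) and HBEGF (log2 1.98), and RASD1 (log2 2.44) rose as well. The alkaline phosphatase ALPP (log2 2.16), the chemokine receptor CXCR4 (log2 2.12), SPP1, osteopontin (log2 2.02), TRIB1 (log2 1.95) and GADD45G (log2 1.94) also rose. The readthrough NME1.NME2 rose (log2 2.08) but lay at 2.79 ± 3.95 FPKM in the controls, and its call was lost with robust moderation (adjusted p = 0.28).

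The deepest falls in HOS were in MTRNR2L genes, nuclear copies of mitochondrial ribosomal RNA. MTRNR2L2 fell from 4634 ± 411 to 136 ± 7.64 FPKM (log2 -5.08), with MTRNR2L8 (log2 -4.81), MTRNR2L10 (log2 -4.78), MTRNR2L1 (log2 -4.68), MTRNR2L9 (log2 -4.33), MTRNR2L6 (log2 -3.82) and MTRNR2L3 (log2 -3.12). These genes took 1.79% ± 0.132 of the listed FPKM in NC and 0.0726% ± 0.0045 in the libraries labelled sgNAT10, and their reads cannot be told from mitochondrial ones in such a table. Smooth muscle actin, ACTA2, fell from 109 ± 10.9 to 10.9 ± 0.55 FPKM (log2 -3.21, SE 0.10, adjusted p = 1.8e-13). The complement protease CFI (log2 -2.13), the stress gene NUPR1 (log2 -2.08), C5orf63 (log2 -2.12) and ADAM33 (log2 -1.83) fell too. The median change over all genes was 0.19, and under median-ratio scaling, which brings it to -0.0079, the split was 3762 higher and 4038 lower. With the spread shared by all 8 libraries, over the 10655 genes tested in both lines, the count was 1864 genes in HOS and 5553 in 143B. Among those 10655 genes the separate HOS fit called 4909 higher and 2474 lower. Most of the fall in the HOS count thus came with the shared spread rather than with the fewer genes.

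Immediate early, inflammatory and matrix genes were higher in the HOS libraries labelled sgNAT10. In HOS, counts adjusted over the list alone were the same as those over all genes for every list. Of 19 immediate early genes 17 rose and 2 fell, FOS (log2 -0.45) and EGR1 (log2 -0.43) being those that fell. KLF6 rose (log2 0.86), with adjusted p = 7.1e-05 for the list and adjusted p = 0.42 with an estimated correlation. Inflammatory genes rose in 16 of 20 cases and fell in 2, with IER3 at 0.86 and CCL5 at -0.64 (adjusted p = 0.0041 for the list; adjusted p = 0.42 with an estimated correlation). YAP targets rose in 15 of 20 cases and fell in 1, including PTPN14 (log2 1.13) and ASAP1 (log2 1.02), with adjusted p = 0.0020 and adjusted p = 0.42 with an estimated correlation. Of 38 matrix and mesenchymal genes 27 rose and 2 fell, PLAU by a log2 change of 1.89 (adjusted p = 0.0028 for the list; adjusted p = 0.42 with an estimated correlation). After length and GC correction 15 rose and 15 fell, the median went from 0.48 to -0.032 and the call was lost (adjusted p = 0.62). Of 11 osteoblast genes 7 rose and 0 fell, MSX2 by 0.96 (adjusted p = 0.014 for the list; adjusted p = 0.42 with an estimated correlation; adjusted p = 0.072 after length and GC correction).

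Genes for ribosomal proteins, aminoacyl-tRNA synthetases, respiration and mitosis were lower in the HOS libraries labelled sgNAT10. Cytosolic ribosomal protein genes fell in 37 of 45 cases and rose in 0 (14 rose and 18 fell under quantile normalization), RPL30 by a log2 change of -0.91 and RPLP0 by -0.44 (adjusted p = 4.5e-13 for the list; adjusted p = 0.42 with an estimated correlation). Under quantile normalization their median was 0.055 and the call was lost (adjusted p = 0.76). Their share of the listed FPKM was 28.0% ± 0.241 in NC and 20.8% ± 0.472 in sgNAT10. Aminoacyl-tRNA synthetases fell in 13 of 20 cases and rose in 2, including CARS (log2 -0.52), SARS (log2 -0.48) and WARS (log2 -0.44), with adjusted p = 7.1e-05 and adjusted p = 0.42 with an estimated correlation. Of 31 respiratory chain genes 21 fell and 3 rose, with NDUFS1 at -0.81 (adjusted p = 2.7e-06 for the list; adjusted p = 0.42 with an estimated correlation). Mitotic genes fell in 20 of 32 cases and rose in 6, PRC1 by -0.96, the checkpoint kinase BUB1 by -0.85 and BUB1B by -0.70 (adjusted p = 1.9e-05 for the list; adjusted p = 0.42 with an estimated correlation). Ribosome biogenesis genes fell in 14 of 34 cases and rose in 8, with NOP58 at -0.68 (adjusted p = 0.014 for the list; adjusted p = 0.42 with an estimated correlation), and their median of -0.12 became 0.090 when libraries were rescaled to a common sum. Interferon-stimulated genes fell in 11 of 28 cases and rose in 6, with IFITM1 at -0.48 (adjusted p = 0.012 for the list; adjusted p = 0.42 with an estimated correlation), and their median of -0.15 became 0.024 when rescaled.

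The ATF4 list was not called in HOS, with 24 of 36 members higher and 5 lower (adjusted p = 0.16). ASNS fell from 87.1 ± 1.34 to 36.8 ± 1.51 FPKM (log2 -1.22, SE 0.09, adjusted p = 1.4e-08) and ATF4 from 441 ± 10.4 to 370 ± 3.98 FPKM (log2 -0.25), whereas DDIT4 (log2 0.80) and PHGDH (log2 0.46) rose. Uncalled lists, as higher and lower members, were hypoxia and glycolysis with 18 and 5 of 30, cholesterol with 11 and 1 of 24, p53 targets with 14 and 2 of 24, and RNA acetylation and modification enzymes with 18 and 9 of 32. Further uncalled lists were DNA replication with 12 and 5 of 30, endoplasmic reticulum chaperones with 3 and 6 of 19, histones with 6 and 4 of 12 and heat shock with 4 and 6 of 15. Their adjusted p by camera lay between 0.12, for hypoxia and glycolysis, and 0.96, for RNA modification enzymes. The heat shock list had a median of -0.12 and a mean of 0.12. The medians of endoplasmic reticulum chaperones (0.050), DNA replication (0.044) and histones (0.21) were positive while the direction of their camera tests, none of them called, was down. DNA replication turned to 8 higher and 13 lower under median-ratio scaling and to 7 and 15 after length and GC correction, and RNA modification enzymes to 11 and 13 under median-ratio scaling. Rescaled to a common sum, endoplasmic reticulum chaperones turned to 10 higher and 4 lower and heat shock to 7 and 4. Epithelial markers were higher in 2 and lower in 2 of 7, blood markers in 1 and 1 of 5, and endothelial, adipose and neural markers in 4 and 1 of 5, none of these lists being called (adjusted p = 0.67, 0.89 and 0.74). The epithelial markers had a median of 0.21 and a mean of -0.13, and the blood markers had a median of 0.087 while the direction of their camera test was down.

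**Figure D2:**
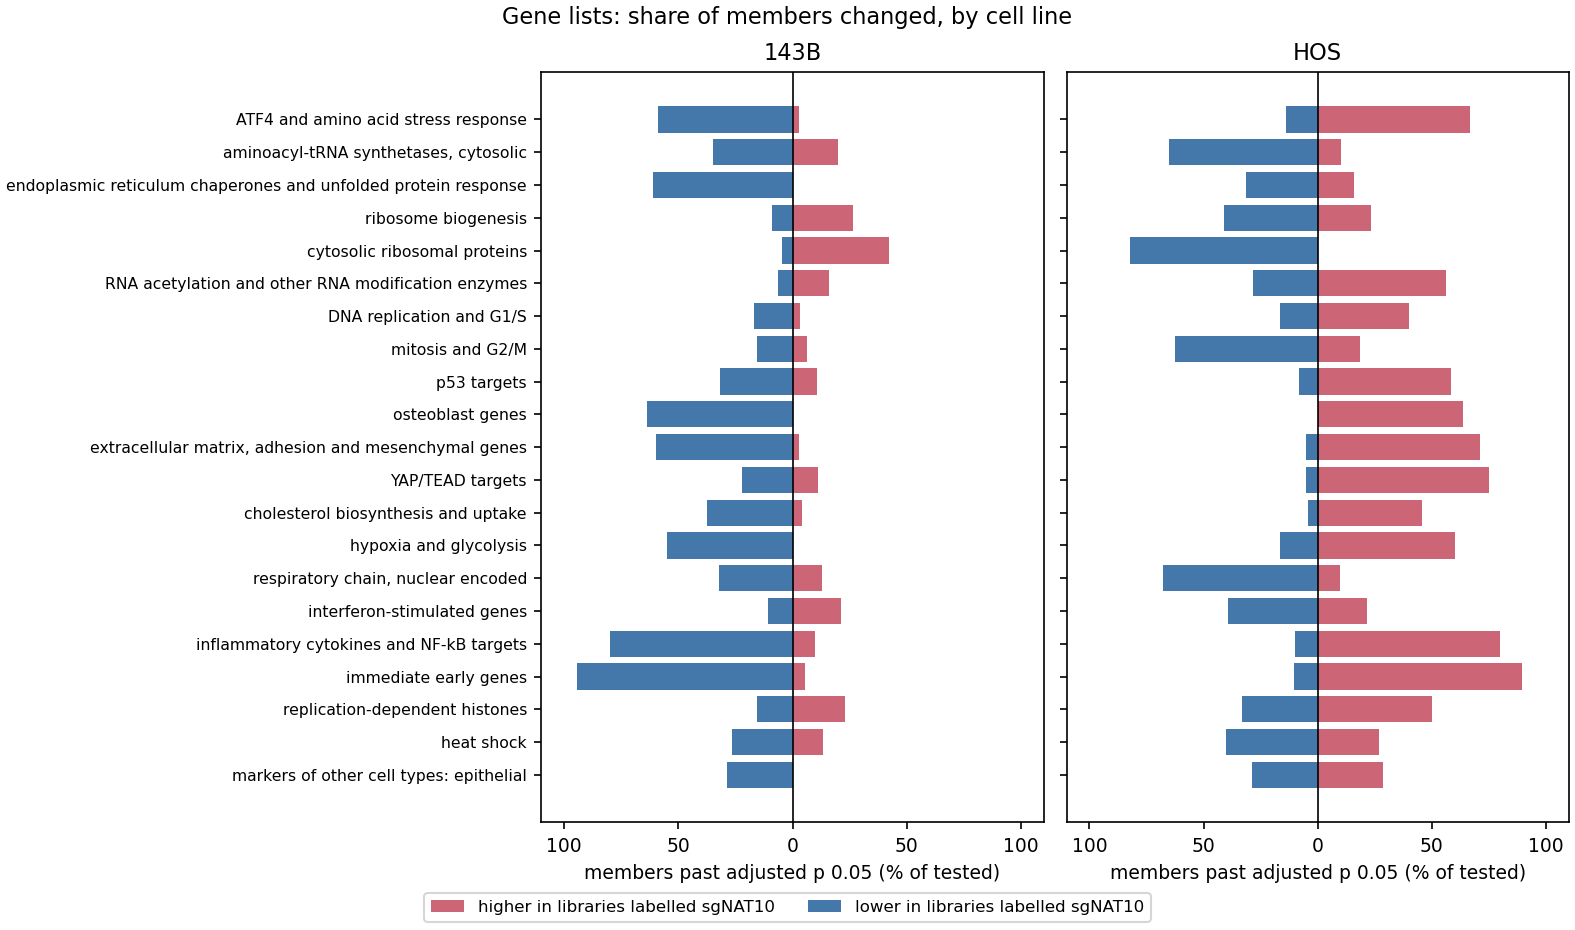
Share of the tested members of each gene list (percent, x axis) that were higher (red, to the right) or lower (blue, to the left) in the libraries labelled sgNAT10, by cell line. Of the immediate early genes 17 of 18 were lower in 143B and 17 of 19 higher in HOS, and of the cytosolic ribosomal protein genes 19 of 45 were higher in 143B and 37 of 45 lower in HOS (under quantile normalization the HOS counts were 14 higher and 18 lower).

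Over both lines together, 3261 of 10655 genes changed, 1391 higher and 1870 lower in the libraries labelled sgNAT10. PTPN14 had the largest mean rise (log2 2.12, SE 0.16, adjusted p = 0.00021), followed by PRKAR2A (log2 2.08) and CAV1 (log2 1.96). CDA, cytidine deaminase, rose from 0.34 ± 0.099 to 4.30 ± 0.537 FPKM in 143B and from 7.86 ± 1.42 to 25.9 ± 0.530 FPKM in HOS (SD, n = 2; log2 1.80 over both). PRR11 (log2 1.80), the kinase ABL2 (log2 1.76), KISS1 (log2 1.76), and the transcription factors NFIB (log2 1.74) and KLF6 (log2 1.71) rose too. The decapping factor DCP1A (log2 1.71), PM20D2 (log2 1.70), HTD2 (log2 1.70) and LOC112268168 (log2 1.70) were also higher. The falls included DHRS3 (log2 -2.41), ACTA2 (log2 -2.16), ACTG2 (log2 -2.04), FOS (log2 -1.69) and the linker histone H1F0 (log2 -1.60). TUBA1A (log2 -1.57), COL9A3 (log2 -1.56), MPLKIP (log2 -1.63) and LOC101929479 (log2 -1.96) were also lower. So was an entry listed as X45174 (log2 -1.63), whose gene was not identified here. MTRNR2L10 (log2 -2.64), RPSAP58 (log2 -2.03) and EIF3C (log2 -1.71) fell as well, with uncertain counting. NAT10 itself was not called over both lines (log2 -0.35, SE 0.14, adjusted p = 0.095), but it was called with the replicate number as a block (adjusted p = 0.014), without 143B NC replicate 1 (0.027) and after length and GC correction (0.027). Without 143B NC replicate 2 the balance turned, with 2481 genes higher and 2188 lower, and under quantile normalization it was 2207 and 2152. The count was 1663 without HOS NC replicate 1, 1399 without HOS NC replicate 2, 1487 without HOS sgNAT10 replicate 1 and 1428 without HOS sgNAT10 replicate 2. It was 6124 with the replicate block and 5966 after length and GC correction, and 475 genes changed by at least 2-fold.

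Among the lists over both lines, endoplasmic reticulum chaperones were lower in 10 of 18 cases and higher in 0 (11 and 1 adjusted over the list alone). HSP90B1 fell in 143B (log2 -1.32) and in HOS (log2 -0.75), and PDIA4 fell by a mean log2 of -1.18, with adjusted p = 0.023 for the list and adjusted p = 0.73 with an estimated correlation. In HOS alone that list was not called, with 3 higher and 6 lower of 19 (camera adjusted p = 0.25). Rescaled to a common sum it had 10 higher and 4 lower in HOS, so this call rests mostly on 143B too. The other 3 calls over both lines average opposite changes and rest on 143B, as their members went mostly the other way in HOS. Hypoxia and glycolysis genes (16 lower and 0 higher in 143B, 5 lower and 18 higher in HOS) were lower in 11 of 29 cases and higher in 0 (13 and 0 adjusted over the list alone), with adjusted p = 0.023, adjusted p = 0.68 with an estimated correlation, and adjusted p = 0.067 without 143B NC replicate 1. Their call was also lost under median-ratio scaling (adjusted p = 0.052) and after length and GC correction (median -0.33 before and -0.25 after, adjusted p = 0.096). Matrix and mesenchymal genes (21 lower and 1 higher in 143B, 2 lower and 27 higher in HOS) were lower in 14 of 34 cases and higher in 2 (15 and 3 adjusted over the list alone), with adjusted p = 0.023, adjusted p = 0.73 with an estimated correlation, and adjusted p = 0.059 without 143B NC replicate 2 and 0.067 with a pseudocount of 5. Ribosomal protein genes (19 higher and 2 lower in 143B, 0 higher and 37 lower in HOS, or 14 and 18 under quantile normalization) were higher in 10 of 45 cases and lower in 5 (11 and 6 adjusted over the list alone), with adjusted p = 0.023, adjusted p = 0.68 with an estimated correlation, and adjusted p = 0.11 without 143B NC replicate 2. That call was lost under median-ratio scaling (adjusted p = 0.052) and quantile normalization (0.20) as well. YBX1 fell in both lines, from 685 ± 69.7 to 462 ± 5.65 FPKM in HOS (log2 -0.56, adjusted p = 2.3e-05) besides its fall in 143B.

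The change differed between the lines for 5235 of 10655 genes, 1375 with a higher change in 143B and 3860 with a higher change in HOS. PLAU fell in 143B and rose in HOS, from 10.1 ± 0.587 to 40.1 ± 0.983 FPKM (SD, n = 2), a difference in log2 change of -5.63 (SE 0.24, adjusted p = 6.6e-06). CDKN1A rose in HOS from 8.55 ± 0.382 to 24.8 ± 1.14 FPKM (difference -5.26), DDIT4 from 43.8 ± 1.83 to 77.3 ± 0.12 FPKM (difference -5.31) and PLAT from 23.6 ± 2.24 to 34.3 ± 1.75 FPKM (difference -5.23), each against a fall in 143B. For NAT10 the difference was -1.41 (SE 0.29, adjusted p = 0.0036), and -0.46 (adjusted p = 0.075) after length and GC correction. The median difference over all genes was -0.44, and under median-ratio scaling, which brings it to 0.0019, the split was 2662 and 2709. Leaving out any 1 library left between 3652 and 6381 genes.

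Among the lists, all 8 osteoblast genes tested in both lines had a lower change in 143B than in HOS, also when adjusted over the list alone. MSX2 stood at -2.72 and ALPL at -2.05 (adjusted p = 0.0044 for the list; adjusted p = 0.33 with an estimated correlation). Lower and higher changes numbered 17 and 1 of 18 for immediate early genes, with DUSP1 at -3.03 (adjusted p = 4.0e-06; adjusted p = 0.33 with an estimated correlation). For inflammatory genes they numbered 14 and 1 of 18, with IER3 at -4.10 (adjusted p = 0.0019; adjusted p = 0.33 with an estimated correlation). Matrix and mesenchymal genes had 27 lower and 1 higher of 34, with MMP1 at -4.52 (adjusted p = 2.1e-05; adjusted p = 0.33 with an estimated correlation). For these 3 lists the counts adjusted over the list alone were the same. The ATF4 list had 23 lower and 0 higher of 34 (24 and 1 adjusted over the list alone), with PHGDH at -3.63 (adjusted p = 0.00050; adjusted p = 0.14 with an estimated correlation). Hypoxia and glycolysis had 22 lower and 0 higher of 29 (22 and 1 adjusted over the list alone), with ANGPTL4 at -4.06 (adjusted p = 0.0019; adjusted p = 0.14 with an estimated correlation). Cholesterol genes had 14 lower and 0 higher of 24 (16 and 2 adjusted over the list alone), with IDI1 at -1.11 (adjusted p = 0.029; adjusted p = 0.33 with an estimated correlation). Ribosomal protein genes had a higher change in 143B in 36 of 45 cases and a lower change in 1, the same as adjusted over the list alone, with adjusted p = 6.0e-17 and adjusted p = 0.068 with an estimated correlation. Under quantile normalization 16 had a higher and 6 a lower change, the median went from 1.38 to 0.32 and the call was lost (adjusted p = 0.13). Ribosome biogenesis genes had a higher change in 8 and a lower change in 4 of 34 cases, the same as adjusted over the list alone, with NOP58 at 2.87 (adjusted p = 0.0046; adjusted p = 0.33 with an estimated correlation). Respiratory chain genes had a higher change in 10 and a lower change in 8 of 31 (11 and 8 adjusted over the list alone; adjusted p = 0.023; adjusted p = 0.33 with an estimated correlation), and mitotic genes in 5 and 6 of 32 (2 and 2 adjusted over the list alone; adjusted p = 0.046; adjusted p = 0.65 with an estimated correlation). The medians of these last 3 lists, of 0.29, 0.33 and 0.14, turned negative when libraries were rescaled to a common sum.

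Across the 10655 genes, which are not independent replicates, the changes in the lines were negatively correlated (Pearson r = -0.24, Spearman rho = -0.25). Genes higher in both lines numbered 361, against 526 if the lists were independent, and those lower in both 291 against 619. Genes lower in 143B and higher in HOS numbered 1677 against 1228 (Fisher's exact test, one-sided p = 9.7e-91, over genes), and the reverse 387 against 265 (one-sided p = 1.9e-18). Both p-values take genes as independent and measure no spread between libraries. After length and GC correction r was -0.085.

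**Figure D3:**
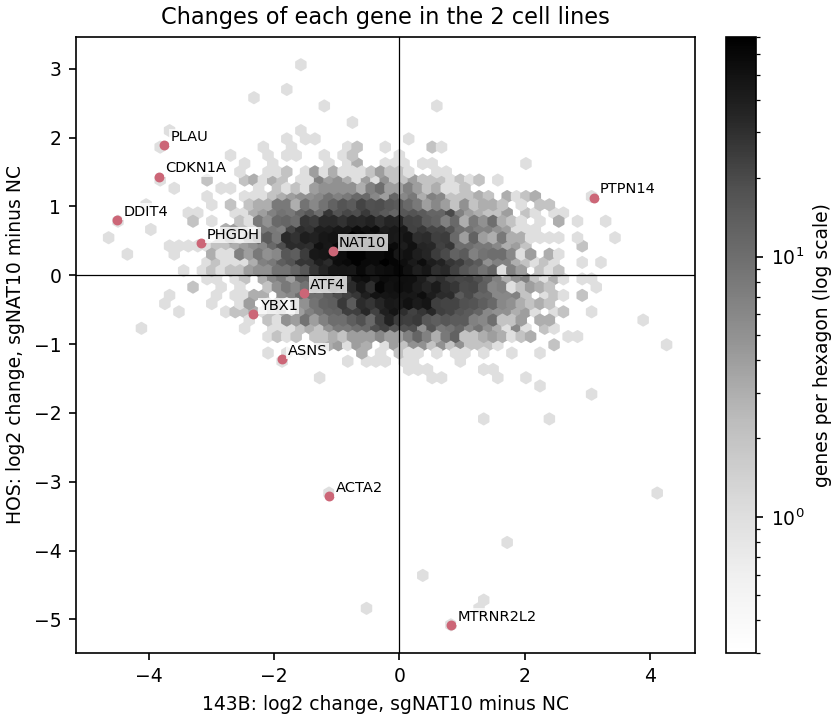
Log2 change of each gene between libraries labelled sgNAT10 and NC in 143B (x axis) and HOS (y axis), as hexagons shaded by the number of genes (log scale), with 11 genes marked. PLAU, CDKN1A and DDIT4 lie at the upper left, lower in 143B and higher in HOS, while ASNS, YBX1 and ACTA2 lie in the lower left quadrant and PTPN14 at the upper right.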

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

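The tests of scaling, of length and GC content and of exchanged labels for NAT10, of length and GC content for the correlation between lines, and the count over other splits of the libraries, were chosen after the results were seen. No group held enough libraries to look for a single library apart from its group.

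The 5235 genes whose change differed between the lines, and the values here, drew attention because the test of the difference itself passed. NAT10 differed by -1.41 on the log2 scale (143B minus HOS). MTRNR2L3 differed by 7.27, MTRNR2L8 by 6.05, MTRNR2L1 by 6.02, MTRNR2L2 by 5.91 and MTRNR2L6 by 5.57, all with reads shared with mitochondrial ribosomal RNA. NME1.NME2 differed by -5.75, and its reads are shared with NME1, which rose in 143B (log2 1.97) and fell in HOS (log2 -0.55), and with NME2. PLAU differed by -5.63, DDIT4 by -5.31, CDKN1A by -5.26 and PLAT by -5.23. Median differences of the lists called as differing were -2.82 for immediate early genes, -2.32 for inflammatory genes, -1.95 for matrix and mesenchymal genes, -1.68 for osteoblast genes, -1.47 for the ATF4 list, -1.31 for hypoxia and glycolysis, -1.07 for cholesterol genes, 1.38 for ribosomal proteins, 0.33 for the respiratory chain, 0.29 for ribosome biogenesis and 0.14 for mitosis. None of these lists was called with an estimated correlation, the lowest value being adjusted p = 0.068 for ribosomal proteins. The last 3 medians were negative when libraries were rescaled to a common sum (-0.21, -0.24 and -0.38).

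NAT10 was not lower in the HOS libraries labelled sgNAT10. Under median-ratio scaling its HOS change was 0.14 (95% interval -0.080 to 0.35) against -0.80 in 143B. After length and GC correction it was -0.077 (-0.22 to 0.067) against -1.06 uncorrected and -0.54 corrected in 143B. Neither this scaling nor this correction thus showed a fall of the size seen in 143B. Median-ratio scaling takes most genes as unchanged, which could not be checked here, so a shift shared by most genes is not excluded. A fall of up to the lower bounds stays possible, and after the correction the difference between lines missed the threshold (log2 -0.46, adjusted p = 0.075). Exchanged HOS labels would give opposite changes in the 2 lines, and r was -0.24, but -0.085 after correction, so labels exchanged in HOS and different responses of the lines cannot be told apart. A knockout that leaves the RNA in place stays open, untested.

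Over all genes the changes in the 2 lines were weakly and negatively correlated, and part of this may come from transcript length and GC content. The log2 change correlated with GC content at a Spearman rho of -0.40 in 143B and 0.30 in HOS. With transcript length the rho was 0.015 in 143B and 0.29 in HOS, so only the GC correlations ran in opposite directions. Removing both trends brought r from -0.24 to -0.085, as that explanation would have it, but a response that follows GC content would look the same, so the cause stays open. The trend as fitted was not the whole cause of the list differences, of which 9 of the 11 kept their call and direction. Length and GC content were taken from a single transcript of each gene, so a remaining trend is not excluded. Their sizes moved: the median difference went from -2.82 to -1.86 for immediate early genes, from -2.32 to -1.61 for inflammatory genes, from -1.95 to -1.27 for matrix and mesenchymal genes, from -1.47 to -0.69 for the ATF4 list, from -1.31 to -0.69 for hypoxia and glycolysis, from -1.68 to -0.96 for osteoblast genes and from -1.07 to -0.74 for cholesterol genes. It went from 0.29 to 0.87 for ribosome biogenesis and from 1.38 to 1.40 for ribosomal proteins, whose median fell to 0.32 under quantile normalization, where the call was lost (adjusted p = 0.13). Calls were lost for mitosis (median 0.14 before and 0.21 after, adjusted p = 0.083) and for the respiratory chain (0.33 and -0.19, adjusted p = 0.77). A response to NAT10 loss that differs between the lines is a hypothesis that stays open with exchanged labels.

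For the 3261 genes changed over both lines, 2 of the 34 splits of the 8 libraries that gave a value called as many genes, the real grouping being 1 of them, so this count does not exclude chance. The other, with 5235 genes, exchanges the labels within 1 line and so counts the differences between lines. It is no random grouping but points to that structure of the libraries, so the count says little about chance. The next highest split called 1405, and 1 split gave no value.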

How the results depend on the processing

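The length and GC correction, the block added to it, the crossed block and the leaving out of ribosomal protein genes were chosen after seeing the data. No called named gene or list turned to the opposite direction of its test, though list medians given with the results changed sign, as did NAT10 in HOS, without a call; 105 tests of named genes and 42 of lists lost a call and 54 and 20 gained one, against 3094 and 1501 on the same side. Among all genes, 242 called in HOS were called in the opposite direction with the length and GC correction, against 5690 in the same one. For the difference between lines these were 65 and 3547. Quantile normalization gave 16 opposite calls in HOS and 1 for the difference. The 2 libraries per group and the unknown depth limit all calls, and a group left with 1 library was assumed to vary like the others. NAT10 in HOS turned to -0.077 with the length and GC correction, with or without the block. It lost its call under median-ratio scaling (0.14), quantile normalization (0.20) and a shared spread (0.35), and without sgNAT10 replicate 1 (0.29). With a library left out it ranged from 0.29 to 0.42. In 143B it lost its call under median-ratio scaling (-0.80), without NC replicate 2 and without either sgNAT10 library. There it ranged from -1.21 to -0.91 with a library left out, and was -0.54 with the length and GC correction. Over both lines NAT10 gained a call with the replicate block (-0.35), without 143B NC replicate 1 (-0.43) and with the length and GC correction (-0.31) and ranged from -0.43 to -0.28; its difference between lines lost the call with that correction (-0.46). Counts moved to 2098 in both lines at 5 FPKM (fewer genes tested), to 688 in HOS and 475 in both lines with a 2-fold threshold, to 1864 in HOS with a shared spread (also fewer genes tested), and to 5966 in both lines with the length and GC correction, which took r to -0.085. With a library left out they ranged from 1995 to 5067 in 143B and from 1399 to 4763 in both lines. Replicate numbers were not taken as pairs: the deviations of same-numbered libraries correlated at 0.61 in 143B and -0.11 in HOS. The replicate block gave 7652 genes in 143B, 7881 in HOS and 6124 in both lines, and 7223 in 143B with the correction. A crossed pairing in HOS gave 8458 genes. Except for the 5 FPKM filter, the fold threshold and the shared spread in HOS, the cause was not tested.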

Other observations

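The tests of the 13 gene families were chosen after values were seen, and not all are detailed. Collagens and tubulins were also called lower by camera in 143B and over both lines. In HOS neither was called, with 10 higher and 4 lower of 22 collagens and 7 higher and 3 lower of 18 tubulins. After length and GC correction both 143B calls were lost (camera adjusted p = 0.089 for collagens and 0.20 for tubulins). The tubulin call over both lines was lost too (0.50). That of collagens was kept (0.0080), and collagens were then called lower in HOS (0.0026). Complement proteins and T-complex chaperonin subunits were called lower and dual-specificity phosphatases higher in HOS. Translation initiation factors were called higher in 143B but not in HOS (18 higher and 16 lower of 54, adjusted p = 0.25). Their 143B call was lost after length and GC correction (camera adjusted p = 0.19). Metallothioneins, chemokines and keratins were not called. With an estimated correlation no family was called. Proteasome subunits were lower in 27 and higher in 6 of 46 cases in the HOS libraries labelled sgNAT10 (median log2 -0.35, camera adjusted p = 1.6e-06; adjusted p = 0.54 with an estimated correlation) and higher in 7 and lower in 1 of 46 in 143B (median 0.36, adjusted p = 0.0016; adjusted p = 0.62 with an estimated correlation). Mitochondrial ribosomal proteins fell in 53 and rose in 9 of 78 cases in HOS (median -0.35, adjusted p = 3.0e-10; adjusted p = 0.54 with an estimated correlation). In 143B they rose in 19 and fell in 12 of 78 (median 0.20, adjusted p = 0.013; adjusted p = 0.72 with an estimated correlation), a call lost after length and GC correction (adjusted p = 0.26). HOX genes were lower in 13 and higher in 1 of 30 cases in 143B (adjusted p = 0.0058) and higher in 22 and lower in 2 of 33 in HOS (adjusted p = 0.030), and with an estimated correlation the values were adjusted p = 0.72 and adjusted p = 0.57. After length and GC correction the HOX call was lost in 143B (adjusted p = 0.099) and kept in HOS (adjusted p = 0.024). Zinc finger genes named ZNF rose in 77 and fell in 14 of 241 cases over both lines (adjusted p = 0.00016; adjusted p = 0.88 with an estimated correlation). That call rests on 143B (adjusted p = 0.00043; adjusted p = 0.72 with an estimated correlation), since in HOS, with 140 higher and 61 lower of 359 and a median of 0.15 against 0.19 over all genes, the family was not called (adjusted p = 0.89), and it differed between lines (adjusted p = 0.011; adjusted p = 0.54 with an estimated correlation).

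Control cells of the lines differed widely in level, without a test, since the tables were made separately. MMP1 stood at 645 ± 254 FPKM (SD, n = 2) in 143B NC and 7.21 ± 1.17 in HOS NC, and PLAU at 456 ± 56.3 and 10.1 ± 0.587. COL1A1 stood at 4.64 ± 1.13 and 345 ± 43.8, and ACTA2 at 2.94 ± 0.071 and 109 ± 10.9.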
